A study of Mus musculus with 6 samples.

How the data were processed

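Bulk RNA-seq of 6 samples of the mouse carcinoma line MOC2 was used, 3 labelled control CRISPR and 3 labelled EphA4 knockout. Per the labels' protocols, the knockout cells are the H3 clone, cells were thawed and passaged 2 times, no treatment was given, RNA was extracted with TRI Reagent, and libraries were made with polyA selection. All samples carry the same batch label. The authors deposited 1 table of raw counts per gene symbol for the whole series, with 55418 symbols and no normalization. The submitters' processing notes name the aligner STAR and the genome build GRCm39, without versions. The counting tool, its strand setting and the annotation are not given in the sources used here. The symbols of the table equal, as a set, those of GENCODE mouse release M21, which is built on an earlier assembly, so no coordinates are printed and chromosomes, gene types and transcript lengths come from that release. Of the tested symbols, 22 stand for more than 1 locus. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical paralogs can be split between them.

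Library totals were 36900259, 35115926 and 41775031 counts in the control samples and 35807059, 36970984 and 37174736 in the knockout-labelled samples, so that 1 count equals 0.0239 to 0.0285 CPM. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio has an exact 95% binomial interval. Floors and intervals cover counting error only. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 4.57 to 9.59 for pairs without EphA4 knockout replicate 3 and 28.5 to 29.7 for pairs with it.

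Genes were filtered with filterByExpr, which kept 15199 of the 28042 genes with any count, scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the only term, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE is the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, except that library totals were used for Col1a1, Col1a2, Col3a1 and the other fibroblast and leukocyte genes of the closing tests, for the nearly absent genes and their median, and for the genes standing out in 1 library. Before the data were examined, 40 gene lists were fixed, and each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists.

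Genes were named by a rule fixed at the same time: Epha4 first; the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 3 and no overlap of the groups, leaving out predicted, pseudogene and non-coding entries; up to 4 called members per list by size of change; and all Eph and ephrin genes with Akt1, Akt2, Cdh1 and Vim among a few single genes. The text prints a part of those per list, and some genes that the rule names are not reported here. The criterion of 10 CPM and 32-fold for nearly absent genes was chosen after the data were seen.

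Alternatives were relative log expression and upper-quartile factors, library size alone, no filter, a filter of 5 CPM in 3 libraries, limma-voom, DESeq2 1.42.0, a replicate block, the 20 highest genes left out, each replicate left out, other thresholds, glmTreat against a fold of 1.5, and for lists camera with an estimated correlation or on ranks, and fry. Leaving out pseudogenes was added after the data were seen.

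The scripts were tested on simulated counts for this comparison over 15199 genes, drawn from the control means, library sizes and per-gene dispersions, with 200 changed genes. Control means under 1 CPM were raised to 1 CPM, so the recovery of genes below that level is not shown. Of 50 changed genes at each fold, 29 were recovered at 1.5-fold, 35 at 2-fold, 36 at 4-fold and 50 at 32-fold, and 7.41% of all calls were false. Of 40 simulated lists, the 1 shifted list was called and no other. Genes were drawn independently and lists at random, so this does not show how the preset correlation performs where members are correlated. In the data the correlation was estimated at 0.69 for the ribosomal protein list. The data also called 71.5% of the tested genes, far more than were changed in the simulation, so the recovery may differ. Figures were drawn with matplotlib 3.10.9.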

Results

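RNA was sequenced from MOC2 cells, a mouse oral squamous carcinoma line free of papillomavirus, in 6 libraries. Of these, 3 are labelled as control CRISPR cells and 3 as cells of 1 EphA4 knockout clone. Polyadenylated RNA was measured as raw read counts per gene, and the totals ran from 35115926 to 41775031 counts per library. The comparison asks which transcripts differ between cells edited at Epha4, a receptor tyrosine kinase bound by ephrins, and control cells, and the series names AKT signalling as its interest.

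Transcripts of the targeted gene were not lower in the knockout-labelled libraries. Epha4, on chromosome 1, had 55.1 ± 4.26 CPM (SD, n = 3) in the control libraries and 99.7 ± 3.27 CPM (SD, n = 3) in the libraries labelled EphA4 knockout. The counts were 1907, 2110 and 2250 in control and 3483, 3815 and 3606 in the knockout-labelled libraries. Epha4 was thus higher there, with a log2 fold change of 0.86 (SE 0.06, adjusted p = 2.1e-06 in edgeR's quasi-likelihood test) and no overlap between the groups. A count over the whole gene does not show whether the edited sequence is present or whether protein is made. Because the target goes against the label, every direction below is that of the libraries labelled EphA4 knockout relative to control, not of a loss of Epha4 transcript.

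The 2 groups differed across most of the transcriptome, with most tested interferon, antigen presentation, chemokine and matrix genes lower in the knockout-labelled libraries and most S phase genes higher. As lists these passed camera with a preset correlation. None did with an estimated one (smallest adjusted p = 0.165), a form of the test that rests on 4 residual degrees of freedom. Of 15199 genes tested, 10867 passed an adjusted p of 0.05 in edgeR, 4963 of them higher and 5904 lower. At an absolute log2 fold change of 1 or more, 4630 genes remained, 1569 higher and 3061 lower. The ranges of the groups did not overlap for 76.1% of the tested genes, against 10% given by chance for 3 against 3. The median log2 fold change over all tested genes was -0.04. This median follows largely from the scaling, so higher and lower are relative to the other transcripts of a library. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

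**Figure D1:**
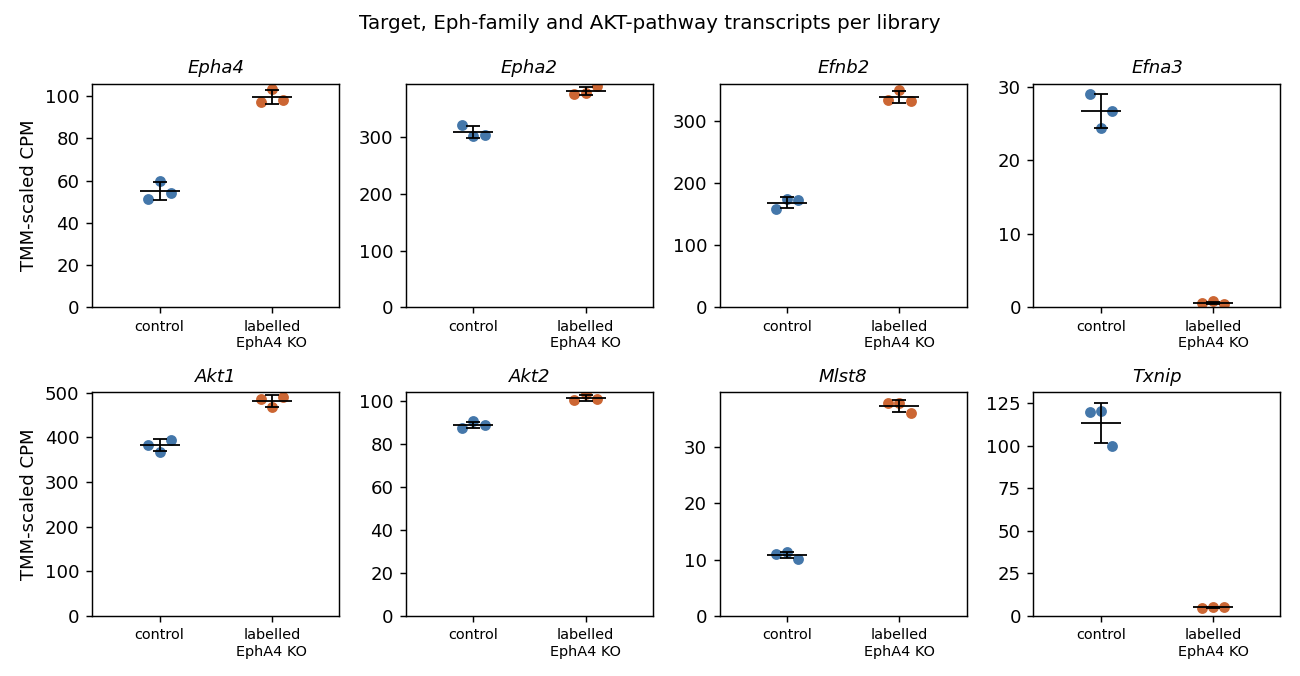
TMM-scaled CPM of 8 transcripts in each library (points), with the mean (horizontal line) and SD (error bar) of the 3 control and the 3 knockout-labelled libraries. Epha4, Epha2, Efnb2, Akt1, Akt2 and Mlst8 are higher in every knockout-labelled library than in any control library, and Efna3 and Txnip are lower.

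The largest rises among genes of at least moderate abundance included several genes of ribosome production. Mdn1, an ATPase of large-subunit maturation, rose 5.52-fold from 45.0 ± 1.07 to 248 ± 6.81 CPM (SD, n = 3 each). Rrp12, another assembly factor, rose 4.73-fold, and Cd3eap, a subunit of RNA polymerase I, rose 7.10-fold. Tfrc, the transferrin receptor for iron uptake, rose 5.49-fold from 85.0 ± 8.95 to 467 ± 2.61 CPM. The water channel gene Aqp8 rose 8.92-fold, to 22.3 ± 2.14 CPM, and the growth factor gene Fgf5 rose 4.92-fold. Tchh, Ccdc86, Bend3, Fmn1, Lbhd1 and Ccnj complete the 12 leading rises, with log2 fold changes from 2.25 for Ccnj to 2.64 for Tchh. Gene models overlap at Cd3eap (with Ercc1), Ccdc86, Tchh, Fmn1 and Lbhd1, so without a stated strand setting their reads cannot be assigned with certainty.

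The 12 leading falls were transcripts found in every control library and almost absent from the knockout-labelled ones. Crabp1, a retinoic acid binding protein gene, had 4570 counts over the control libraries and 0 counts in all 3 knockout-labelled libraries, at least 1472-fold lower against a floor of 3 counts over the group. The collagen gene Col5a3 was at least 1429-fold lower and the interferon-induced Oas2 at least 1367-fold lower. H2-Q7, a class Ib histocompatibility gene with near-identical relatives, was at least 1187-fold lower. Trim30a, Galnt18, Ddx60, Armcx1, Khdrbs3, Eml2 and Bhlhb9 also had 0 counts there, and were lower by at least 589-fold (Bhlhb9) to at least 1090-fold (Trim30a). Ifi44 kept 2 counts and was 3544-fold lower, with a 95% counting interval of 981 to 29268. Reads of Trim30a and Bhlhb9 can fall in overlapping gene models. The loss was one-sided: 178 genes with at least 10 CPM in every control library were over 32-fold lower in the knockout-labelled libraries, and 0 genes met the mirrored criterion.

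**Figure D2:**
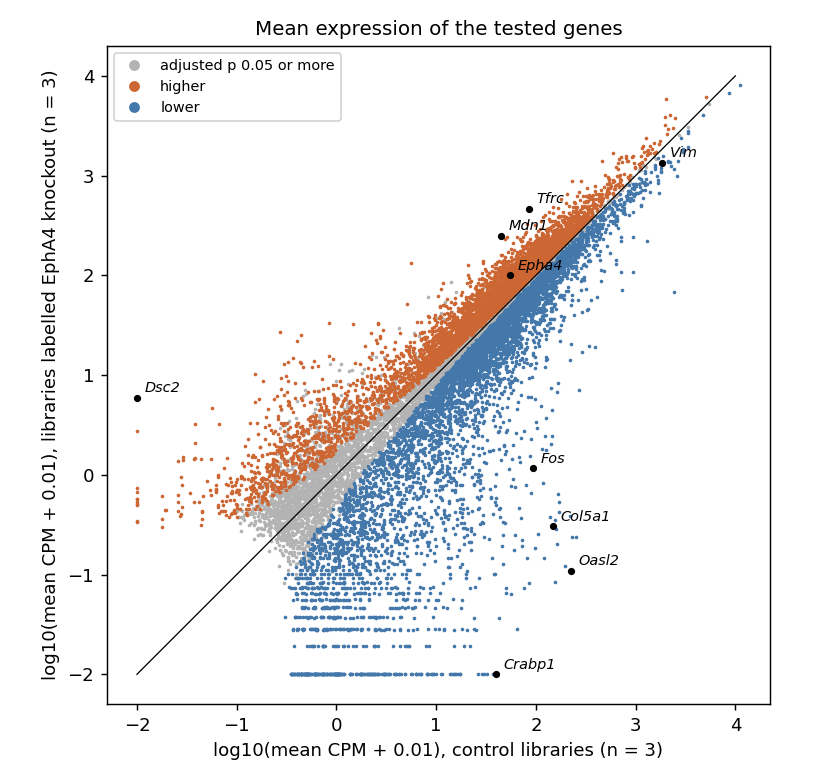
Mean CPM of each tested gene in the control libraries (horizontal axis) and the knockout-labelled libraries (vertical axis), both as log10 of the mean plus 0.01, with n = 3 each and the line of equality. Points below the line spread much further than those above it, down to Crabp1 with 0 counts in the knockout-labelled libraries.

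Within the Eph receptors and ephrins, 5 of 16 tested members rose, 7 fell and 4 did not pass. Besides Epha4, the ligand genes Efnb3 (log2 fold change 1.15), Efnb2 (1.01) and Efna5 (0.65) and the receptor gene Epha2 (0.30) rose. Efna3 fell furthest, from 26.7 ± 2.32 to 0.56 ± 0.18 CPM (SD, n = 3 each). Efna2 (log2 fold change -3.34), Epha7 (-3.32), Ephb6 (-1.43), Efna1 (-1.17), Efna4 (-0.75) and Ephb4 (-0.43) also fell. Epha1, Ephb2, Ephb3 and Efnb1 had log2 fold changes of -0.12, 0.23, 0.00 and -0.39 and did not pass, although Efnb1 passed as lower with limma-voom, with a filter of 5 CPM in 3 libraries, with pseudogenes left out and without EphA4 knockout replicate 2. The list as a whole did not pass camera (adjusted p = 0.74).

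Of 30 tested components of the PI3K-AKT-mTOR pathway, 16 rose, 8 fell and 6 did not pass, or 16 and 9 adjusted over the list alone. The kinase genes Akt1 and Akt2 rose by log2 fold changes of 0.33 (SE 0.04) and 0.19 (SE 0.04). The mTOR subunit gene Mlst8 rose (log2 fold change 1.79), and Pik3cd, Foxo4 and Eif4ebp1 fell (-2.46, -1.45 and -1.27). The list did not pass camera (adjusted p = 0.23), and its median of 0.23 and mean of -0.03 differ in sign. Targets of FOXO factors, which AKT holds out of the nucleus, were lower: 2 of 22 rose and 16 fell, with an adjusted p of 0.0051 in camera and of 0.197 with an estimated correlation. Txnip, an inhibitor of glucose uptake, fell from 113 ± 11.9 to 4.87 ± 0.16 CPM, and Pik3ip1, Sesn3 and Gadd45a fell by 2.87, 2.52 and 2.33 on the log2 scale. These are transcripts, and AKT phosphorylation was not measured.

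Interferon-induced genes were almost all lower. Of 33 tested genes of the type I interferon response, 32 fell and 1 rose, with a median log2 fold change of -7.15, or -6.66 with genes at 0 counts set to their bound. Oasl2 fell from 226 ± 27.3 to 0.10 ± 0.10 CPM (SD, n = 3 each). The list passed camera (adjusted p = 1.9e-10), and had an adjusted p of 0.165 with an estimated correlation. Antigen presentation followed: 17 of 21 genes fell and 1 rose (camera adjusted p = 0.00012, and adjusted p = 0.174 with an estimated correlation). The peptide transporter gene Tap1 fell from 72.9 ± 8.21 to 0.21 ± 0.16 CPM and the immunoproteasome gene Psmb8 from 27.2 ± 0.89 to 0.08 ± 0.03 CPM. Psmb9 kept 2 counts and was 651-fold lower (95% counting interval 180 to 5379). Nlrc5, an activator of class I genes, fell by 5.91 on the log2 scale. Reads of the Oas and class I families can be shared between near-identical copies, so single members are uncertain.

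Chemokine and cytokine transcripts fell in 26 of 29 tested members, and 1 rose (camera adjusted p = 2.1e-07, and adjusted p = 0.165 with an estimated correlation). Ccl2, which attracts monocytes, fell from 195 ± 15.7 to 0.11 ± 0.12 CPM (SD, n = 3 each), and Il33 was at least 418-fold lower. Targets of NF-kB were lower in 18 of 24 members and higher in 6 (camera adjusted p = 0.0031, and adjusted p = 0.165 with an estimated correlation). Lcn2 and Tnfaip2 fell from 138 ± 23.5 and 155 ± 5.22 CPM to 0.37 ± 0.14 and 0.34 ± 0.24 CPM. Immune checkpoint ligands and immunomodulators fell in 16 of 21 members and rose in 3 (camera adjusted p = 0.0017, and adjusted p = 0.187 with an estimated correlation). The NKG2D ligand genes Raet1d and H60b were at least 348-fold and at least 126-fold lower, and Arg1 fell from 71.3 ± 5.70 to 2.35 ± 0.27 CPM.

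Mesenchymal and matrix transcripts fell as well. Of 17 tested mesenchymal genes 14 fell and 0 rose, with a median log2 fold change of -2.20 (camera adjusted p = 0.0012, and adjusted p = 0.165 with an estimated correlation). Twist2 fell from 61.6 ± 2.28 to 0.24 ± 0.19 CPM (SD, n = 3 each) and Snai2 fell by 4.87 on the log2 scale, while Vim fell by only 0.46. Collagens and matrix glycoproteins fell in 20 of 28 members and rose in 6, or 21 and 6 adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.312 with an estimated correlation). Col5a1 fell from 148 ± 6.93 to 0.29 ± 0.14 CPM. Matrix proteases and their inhibitors fell in 21 of 28 members and rose in 3 (camera adjusted p = 0.0013, and adjusted p = 0.187 with an estimated correlation), with Serpine2 at least 558-fold lower. TGF-beta targets fell in 17 of 23 and rose in 4 (camera adjusted p = 0.0036, and adjusted p = 0.174 with an estimated correlation), Ltbp2 by 6.09 on the log2 scale. Markers of fibroblasts and pericytes moved with these groups, all 8 tested members, 5 of them also in another list, being lower (camera adjusted p = 0.001, and adjusted p = 0.165 with an estimated correlation). In the control libraries Col1a1 and Col3a1 had 14.8 and 20.6 CPM, while Col1a2, the partner chain of Col1a1, had 0.0441 CPM.

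Epithelial genes went both ways. Of 32 junction genes 14 rose, 15 fell and 3 did not pass, and the list did not pass camera (adjusted p = 0.60). The desmosome gene Dsc2 had 0 counts in every control library and 5.94 ± 0.81 CPM (SD, n = 3) in the knockout-labelled ones, at least 224-fold higher. Cdh1, which encodes E-cadherin, rose by a log2 fold change of 0.14, a call lost with no filter on low counts (log2 fold change 0.08), and Tjp3 and Cldn1 fell by 3.61 and 1.62 on the log2 scale. Squamous basal and differentiation genes had 8 higher and 13 lower of 23 (camera adjusted p = 0.50), with Sprr1a falling from 143 ± 2.56 to 2.03 ± 0.69 CPM. Among genes associated with cancer stem cells, 5 of 17 rose and 11 fell (camera adjusted p = 0.28), and Alcam fell by 5.33 on the log2 scale.

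Proliferation transcripts were higher. Of 32 S phase genes 27 rose and 0 fell, with a median log2 fold change of 0.89 (camera adjusted p = 1.6e-08, and adjusted p = 0.165 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose 2.85-fold from 166 ± 9.51 to 474 ± 4.83 CPM (SD, n = 3 each), and the cyclin gene Ccne2 rose 4.53-fold. G2 and M phase genes rose in 22 of 31 members and fell in 7 (camera adjusted p = 0.0037, and adjusted p = 0.295 with an estimated correlation), with Ccnf rising and Ccnb2 falling (log2 fold changes 1.10 and -1.22). The cell cycle inhibitor gene Cdkn1a fell from 58.2 ± 1.17 to 13.4 ± 0.28 CPM, in a list of p53 targets with 7 higher and 12 lower of 22 (camera adjusted p = 0.50). Immediate early genes fell in 20 of 21 members and rose in 0 (camera adjusted p = 5.5e-05, and adjusted p = 0.174 with an estimated correlation), with Fos falling from 94.4 ± 8.49 to 1.16 ± 0.21 CPM. Targets of the ERK pathway had 6 higher and 12 lower of 20 (camera adjusted p = 0.32), Dusp6 falling and Dusp5 rising.

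Stress and metabolic lists were mostly lower. The hypoxia response fell in 15 of 20 members and rose in 3 (camera adjusted p = 0.0026, and adjusted p = 0.165 with an estimated correlation), with Ddit4 falling from 289 ± 11.2 to 17.2 ± 1.18 CPM (SD, n = 3 each) and P4ha2 from 87.7 ± 7.80 to 1.53 ± 0.64 CPM. Targets of ATF4 and the unfolded protein response fell in 22 of 29 and rose in 2 (camera adjusted p = 0.0005, and adjusted p = 0.197 with an estimated correlation), Nupr1 by 4.25 on the log2 scale. Targets of NRF2 fell in 18 of 24 and rose in 4 (camera adjusted p = 0.0049, and adjusted p = 0.180 with an estimated correlation). Glycolysis genes fell in 12 of 20 and rose in 3 (camera adjusted p = 0.019, and adjusted p = 0.180 with an estimated correlation); the camera call was lost without EphA4 knockout replicate 3 (adjusted p = 0.065). Nuclear genes of oxidative phosphorylation fell in 26 of 33 and rose in 2, with a median of -0.34 (camera adjusted p = 0.0027, and adjusted p = 0.388 with an estimated correlation). Cytosolic ribosomal protein genes fell in 48 of 50 and rose in 0, with a median of -0.51 (camera adjusted p = 4.4e-07, and adjusted p = 0.429 with an estimated correlation); across genes, shorter transcripts tended to lower fold changes (Spearman's rho 0.162 over 12543 genes, which are not independent replicates). Cholesterol and fatty acid synthesis had 18 higher and 8 lower of 30 (camera adjusted p = 0.059, though passing under some other settings), a median of 0.19 and a mean of -0.06. Fasn rose from 708 ± 32.4 to 1530 ± 18.5 CPM and Scd1 fell from 258 ± 2.95 to 93.2 ± 2.90 CPM. Heat shock genes had 9 higher and 4 lower of 15 (camera adjusted p = 0.23), with a median of 0.24 and a mean of -0.37.

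Mitochondrially encoded genes had 9 higher and 1 lower of 13, and the list did not pass camera (adjusted p = 0.094), though it passed with no filter and without EphA4 knockout replicate 1. The leading members rest on 1 library: mt-Nd4l, mt-Nd3 and mt-Atp8 had 561, 485 and 719 counts in EphA4 knockout replicate 3, and without it their log2 fold changes of 4.02, 3.77 and 3.54 became 0.24, 0.10 and -0.19, none passing. That library also set mt-Atp6, mt-Co2 and mt-Co3 apart, at 94.3, 112 and 50.7 CPM by library totals. In the other 2 knockout-labelled libraries mt-Atp6 had 7.74 and 8.09 CPM, mt-Co2 8.38 and 7.79 CPM and mt-Co3 3.91 and 4.36 CPM, each below every control library (lowest 9.23, 13.1 and 6.27 CPM). The same library held 1.41% of its counts in processed pseudogenes, against 0.255% to 0.307% in the other 5.

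Semaphorins, plexins, netrins and Slit-Robo genes fell in 21 of 27 members and rose in 5 (camera adjusted p = 0.0079, and adjusted p = 0.329 with an estimated correlation), with Plxna2 falling from 27.1 ± 1.07 to 0.96 ± 0.56 CPM (SD, n = 3 each). Wnt targets fell in 15 of 22 and rose in 4 (camera adjusted p = 0.045, and adjusted p = 0.327 with an estimated correlation), Wnt10a from 49.7 ± 2.15 to 0.06 ± 0.05 CPM. Their camera call was lost without EphA4 knockout replicate 3 (adjusted p = 0.051). It was also lost with the replicate block, in limma-voom, with a filter of 5 CPM in 3 libraries and with pseudogenes left out. Lists that did not pass camera were the receptor tyrosine kinases and ligands (10 higher and 16 lower of 31, adjusted p = 0.32), integrins (4 and 10 of 15, adjusted p = 0.25), apoptosis regulators (4 and 15 of 21, adjusted p = 0.061), YAP-TEAD targets (9 and 8 of 24, adjusted p = 0.45) and Notch genes (4 and 8 of 15, adjusted p = 0.68). Receptor tyrosine kinases and integrins passed with no filter. Apoptosis regulators passed with no filter, in limma-voom, with the replicate block and without control replicate 1 or 3. Ddr2 fell and Fgfr2 rose among the kinases (log2 fold changes -5.32 and 3.91), Itgb7 fell and Itga8 rose among the integrins (-3.36 and 4.20), and Bmf fell among the apoptosis regulators (-4.06). Hey2, a Notch target with 3 counts in control, was 79.0-fold higher (95% counting interval 26.7 to 386), and Notch3 fell by 4.55 on the log2 scale. Ccn2, a YAP target, fell from 412 ± 15.7 to 160 ± 8.28 CPM, and the YAP-TEAD list had a median of 0.07 and a mean of -0.33. Leukocyte markers had 1 higher and 2 lower of 4 tested (1 and 3 adjusted over the list alone, camera adjusted p = 0.36), endothelial markers 0 and 3 of 5 (adjusted p = 0.23), and skeletal muscle markers 1 and 2 of 6 (1 and 1 adjusted over the list alone, adjusted p = 0.98).

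**Figure D3:**
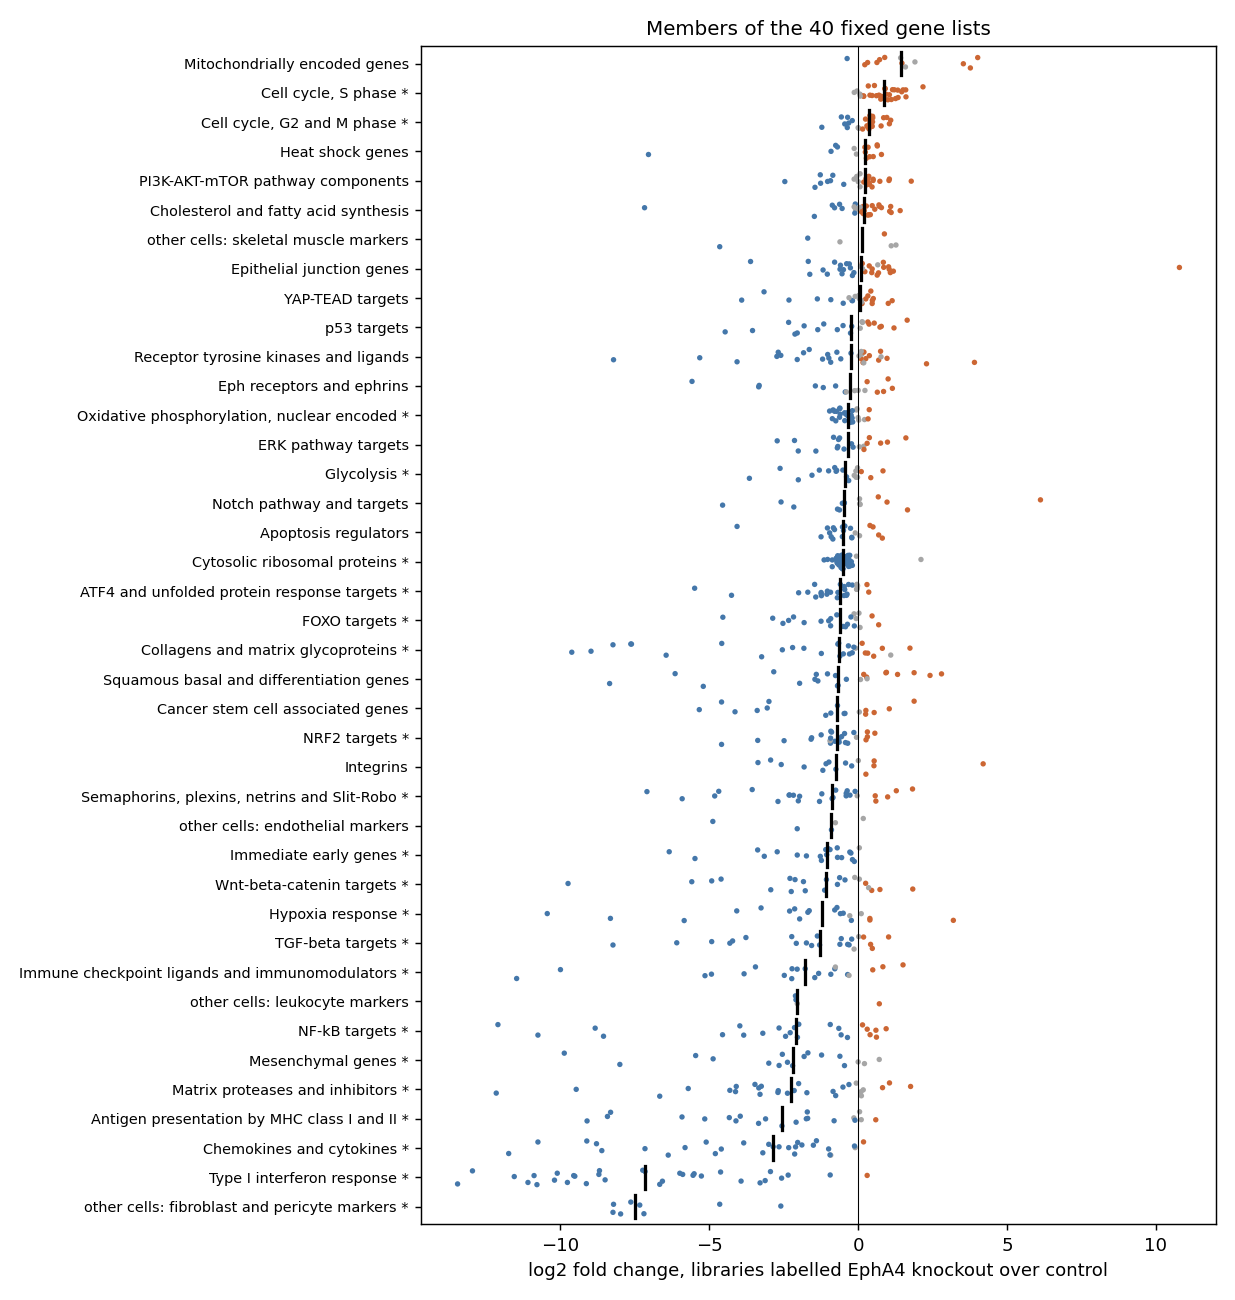
Log2 fold change of each tested member (points) of the 40 gene lists in the libraries labelled EphA4 knockout over control, with the list median as a vertical bar; orange and blue points are genes called higher and lower, grey points are not called, and an asterisk marks a camera adjusted p under 0.05 at a preset correlation. Interferon response genes lie almost wholly to the left, with a median of -7.15, and S phase genes to the right, with a median of 0.89.

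In all, 22 of 40 lists passed camera with a preset correlation of 0.01. With a correlation estimated from each list 0 passed, and the smallest adjusted p was 0.165. That form of camera rests on the 4 residual degrees of freedom of these libraries. For mesenchymal genes the estimated correlation was 0.0099, close to the preset one, yet camera's unadjusted p went from 0.00027 to 0.022. The lack of passing lists therefore cannot be laid to correlation between members alone. By fry, which asks only whether the members of a list move one way, 37 lists passed. The counts adjusted over the list alone equal those over all genes except where both are given. The knockout-labelled cells are 1 clone, so genotype and clone cannot be separated by these libraries.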

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

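The setting without pseudogenes was chosen after the data were seen; the others were planned. Under other scalings, filters and tools the count of genes differing ran from 8681 (at least 5 CPM in 3 libraries) to 11227 (no filter), against 10867, and Epha4 stayed higher in the knockout-labelled libraries, with log2 fold changes from 0.79 (no filter) to 0.91 (pseudogenes left out). The count moved by over 1.5 times under stricter thresholds: 4630 genes at an absolute log2 fold change of at least 1 (1569 higher, 3061 lower) and 5473 by glmTreat against a fold of 1.5 (2006 higher, 3467 lower), as a stricter threshold must give fewer. Leaving out each replicate in turn gave 10045 to 11338 genes, 4675 to 5309 of them higher and 5330 to 6029 lower, log2 fold changes of Epha4 of 0.86 to 0.95, and 21 to 24 lists. Of the lists, 0 passed camera with an estimated correlation, 37 passed fry and 40 passed fry in either direction, tests that ask another question than camera.

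The labels do not say whether the shared sample numbers pair the samples. Deviations of same-numbered samples correlated at -0.003, 0.029 and 0.008, so no strong shared effect was visible, though weak pairing cannot be excluded. With a replicate block 10339 genes were called, Epha4 had a log2 fold change of 0.86 and 22 lists passed, with the Wnt targets losing their call (adjusted p = 0.057) and the apoptosis regulators gaining one (adjusted p = 0.047). Over the settings with the preset correlation the adjusted p ran from 0.0061 to 0.243 for the gene list Wnt-beta-catenin targets and from 0.0047 to 0.106 for the gene list Apoptosis regulators.

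Of 188 named genes, 8 changed call or direction under some alternative: Hspa1a, Tnnc2, Notch4, Cdh1, Efnb1, mt-Nd4l, mt-Nd3 and mt-Atp8. Only mt-Atp8 reversed: leaving out each replicate in turn gave log2 fold changes from -0.19, without EphA4 knockout replicate 3, to 4.09, without EphA4 knockout replicate 2, since most of its counts come from replicate 3. Apart from the set test alternatives, 7 lists changed call under some setting. The Wnt targets lost theirs with at least 5 CPM in 3 libraries, in limma-voom, with the replicate block, without pseudogenes and without EphA4 knockout replicate 3, and glycolysis without that replicate. Calls were gained by receptor tyrosine kinases and integrins (no filter), mitochondrially encoded genes (no filter, and without EphA4 knockout replicate 1), apoptosis regulators (no filter, limma-voom, the block, and without control replicate 1 or 3) and cholesterol synthesis (limma-voom, without pseudogenes, and without control replicate 1 or 3 or EphA4 knockout replicate 3). Low counts limit the genes near the floor, where a difference of 1 count is a large ratio.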

Other observations

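The tests of ribosome assembly, of exchanged labels and of deleted genes were chosen only after the results were seen, as were the 3 gene lists of the next paragraph. Directions are those of the libraries labelled EphA4 knockout, in which Epha4 transcript is higher.

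Genes that build ribosomes were mostly higher. Of 68 tested factors of ribosome assembly and RNA polymerase I, drawn up without Mdn1, Rrp12, Ccdc86 and Cd3eap, 63 were called higher and 4 lower in edgeR, with a median log2 fold change of 0.87. Nolc1 rose from 285 ± 6.84 to 887 ± 21.1 CPM (SD, n = 3 each) and Polr1a from 72.0 ± 2.61 to 172 ± 1.49 CPM. Genes of nucleotide and polyamine synthesis, many of them known Myc targets, were higher in 15 of 19 and lower in 1, with Cad, the first enzyme of pyrimidine synthesis, rising from 147 ± 2.59 to 418 ± 4.40 CPM. Hox genes, which hold positional identity, were lower in 17 of 23 tested and higher in 1: Hoxb9 fell from 222 ± 6.84 to 0.38 ± 0.14 CPM, while Hoxd8 rose. Camera gave unadjusted p values of 2.9e-17, 9.9e-06 and 0.00034 for these lists, and 0.025, 0.085 and 0.017 with an estimated correlation. All 3 lists were drawn up after the results were seen, Hoxb7, Hoxb8 and Hoxb9 among them, so none of these p values is independent evidence. The hypothesis that ribosome assembly genes are higher as a group called for over 70% of the members to be called higher. Of the members 92.65% were, while 4963 of all 15199 tested genes were called higher. Since list and bound followed the largest rises in these same data, this describes the group and does not test the hypothesis.

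Epha4 transcript was higher in the libraries labelled EphA4 knockout. Extra copies of the surrounding segment are argued against, since the 40 nearest tested genes on chromosome 1 had a median log2 fold change of -0.4047, below the bound of 0.3 set beforehand. Whole groups with exchanged labels cannot be told apart from an edit that leaves the transcript in place, since the lowest Epha4 level of any library was 51.44 CPM and neither group lacks the transcript. An edit that changes the protein and not the transcript level would not by itself give this rise, and whether it is present was not tested. A difference between clone and parent was not tested and stays open.

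A set of 178 genes was expressed in control and nearly absent from the knockout-labelled libraries, on 19 chromosomes, and 21.35% of them had a nearly absent neighbour, against a median of 2.25% for random lists, whose central 95% reached 5.62%. Leukocytes in the control cultures are argued against, since 5 abundant leukocyte genes had a median of 0.0265 CPM there. The nearly absent genes had a median of 27.5 CPM there, but their selection at 10 CPM or more ensured a high level. Fibroblasts stay open by the criterion set beforehand, as 6 fibroblast genes had a median of 5.13 CPM, between its bounds of 1 and 10; Col1a2, Dcn and Lum had 0.0441, 0.84 and 0 CPM there, which were looked at afterwards. Of the 178, 135 (75.84%) keep more reads than the stray share of 0.0679% of the control level that Crabp1, at 0 counts, allows. This argues against deletion of whole genes in every cell for those of the 135 whose reads are their own. Crabp1 alone sets that share, which does not cover reads shared with near-identical relatives, as in the Oas and class I families. Some members keep few reads, as Col1a1 with 5, 0 and 0 counts in the 3 knockout-labelled libraries. For the other 43 deletion cannot be told apart from silencing. Of them 27.91% had such a neighbour (95% Wilson interval 16.8 to 42.7, which holds the bound of 25%), against a median of 2.33% for random lists. Random lists do not keep related genes together, and the 178 hold families such as the Oas, Ifit and Hoxb genes. Neighbouring losses therefore cannot separate deletion from a shared change of such families. Silencing, another subclone of the line and the edit itself were not tested.

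Ribosomal protein and oxidative phosphorylation genes were lower, and fold changes rose with transcript length, from a median log2 of -0.32 in the shortest of 5 equal classes to 0.16 in the longest. After a trend with length was removed, the oxidative phosphorylation list had a median residual of -0.09175, only narrowly past the bound set beforehand. The length trend may thus account for its lower level, but the quartiles of its residuals were -0.34 and 0.06, so many members stayed below the trend. The ribosomal protein list kept a median residual of -0.2432, between the bounds set beforehand, so the criterion did not decide. The quartiles of its residuals were -0.37 and -0.04, so most members stayed below the trend. The correlation between these members was estimated at 0.69, so they are not independent evidence of a shift beyond the trend. What makes the length trend, in the RNA or in the cells, was not tested.

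A difference in chromosome copy number between clone and control cells is a hypothesis for shifts of whole chromosomes. Chromosome 14 had a median log2 fold change of -0.4038, past the bound of 0.3 set beforehand, with 71 genes called higher and 268 lower. Chromosome 18 had -0.32, while chromosomes 3 and 19 had 0.28 each. The chromosomes named do not stand alone, since 14 of 20 had medians outside the 95% range of 10000 shuffles. Such shifts may come from copy number, and DNA was not measured here.

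Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 10867 called genes, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached. Each other split also mixes control and knockout-labelled libraries on both sides. Its 0 calls therefore do not show what groups without a difference would give. In EphA4 knockout replicate 3, 465 genes lay at least 4-fold above every other library at 5 CPM or more, 451 of them pseudogenes.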
